A study of Drosophila melanogaster with 2 samples.

How the data were processed

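The data are chromatin immunoprecipitation peak lists from whole adult male flies of 1 transgenic line, with 2 biological replicates per the labels. DNA was fragmented by sonication to 200-800 bp and recovered with an antibody against GFP, per the labels. The authors deposited, for each of the dm6 and dm3 builds, 1 list per replicate, 1 pooled list and 1 thresholded list. The replicate and pooled lists hold 30000 peaks each and served the authors as input to an irreproducible discovery rate (IDR) threshold, per the file headers and labels; such lists include background by design. Peaks were called against a control, per the accompanying notes of the authors. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here, and the control library was not analysed here. No list from a mock immunoprecipitation with the antibody against GFP was used here.

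Each deposited peak carries a signal value from the authors' peak caller, whose scaling is not stated in the deposited lists, and the −log10 of a q-value, deposited beside it. Signal values were used to rank, filter and describe peaks within a list, and ratios of them between replicates were compared only between sets of peaks of the same lists. The exception was a planned count of dm3 and dm6 peaks above 1 shared signal value, which assumes a common scale. The peak lists give no read counts, so the depth of each library is unknown, and a weaker library can have fewer true peaks among its 30000. The −log10 q-value is saturated in the thresholded list, where 4776 of 6066 peaks hold its highest value. All 6066 dm6 thresholded peaks are also in the pooled list with the same position and signal. That selection uses the pooled signal, which combines both replicates, and so narrows the range over which replicates can be compared.

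Positions were read on dm6 and set against the Ensembl release 115 annotation, whose chromosome arms fit the ends of the dm6 peaks. Arms 2L, 2R, 3L, 3R, 4 and X were used. The dm3 peaks were counted and no coordinates were converted. Summits were taken from the deposited summit offset. A summit within 500 bp of a protein-coding transcript start was called a promoter summit, and other summits were assigned in the order 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic.

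Chance placement came from 200 random circular shifts of the peaks along each arm, so that the smallest p is 0.00498, and these permutation tests are one-sided. Shares carry 95% Wilson intervals. Gene sets, the X and divergent pairs were compared with Fisher's exact test, two-sided, with odds ratios and intervals computed after adding 0.5 to each cell. Lists of fewer than 5 members in the annotation would not have been tested. Motifs on either strand were compared between the 200 bp at each summit and a flank of the same size centred 500 bp to 1 side, by the exact McNemar test, two-sided. Words of 8 bases were ranked on 2L and 2R and the leading 10 tested on 3L, 3R and X. Adjusted p-values follow Benjamini and Hochberg over the 24 lists, the 24 motifs or the 10 words. The interval of the rank correlation came from 1000 bootstrap samples of peaks.

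The gene lists, motifs, tests, distances and the rule for named genes were chosen before the data were examined. The rule named CG12768, the genes of the 25 thresholded promoter peaks of highest signal found in both replicates' lists, up to 4 members of each list with the strongest bound promoter, and the 5 strongest peaks over 2000 bp from every protein-coding start. Peaks between 500 and 2000 bp from a start, the strongest of the list among them, fall in neither set. List members were matched by gene symbol, and symbols absent from the annotation were left out. Lists came from general knowledge and some hold genes of wider use, such as cher among male germline genes and the Npc2 sterol carriers among digestive enzymes. In the MADF-BESS list 17 of 19 members were similar in sequence to CG12768 in a search with HMMER 3.4 (jackhmmer, 3 rounds, E-value 1e-05), and bwa and Su(var)3-7 were not.

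Alternatives tried were promoter distances of 250 and 1000 bp, the 3033 peaks of highest signal, each replicate's own 6066 leading peaks in place of the thresholded list, a 100 bp motif window, other flanks and matched promoters, other overlap rules, other backgrounds, list members within 10 kb counted once and the dm3 build. Added after seeing the data were the assignment of each summit to its nearest start, the 1000 strongest peaks for motifs and words, shifts within the span of the thresholded summits, a rank correlation over the pooled list, a MADF family defined by sequence similarity, the MADF families without CG12768, and the gene lists without the histone genes, whose cluster holds no summit of any list. Because the IDR score was not informative in the deposited lists, peaks at the highest −log10 q-value stood in for a stricter threshold.

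The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, biopython 1.88 and matplotlib 3.10.9. They were tested on simulated data. Of 3000 simulated summits made with a promoter share of 40%, 40% were found at promoters. In a list of 200 genes, each drawn as bound with a chance of 60%, 55.5% were bound. A motif planted in 5% of 6000 sequences gave an excess of 4.73%, with 0 of 22 unplanted motifs called. These sequences were random bases of the same composition at summits and flanks. The simulations therefore check the calculations and do not give the rate of false motif calls in real promoter sequence.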

Results

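Chromatin immunoprecipitation with sequencing was used to map where CG12768, a protein with a MADF domain of the Adf1 type, sits on the genome of whole adult male *Drosophila melanogaster*. The flies carried a transgene that expresses CG12768 with GFP at its C terminus, and an antibody against GFP recovered the bound DNA. There were 2 biological replicates of 1 group and no second group, so the comparisons are between the replicates, between kinds of sequence and between sets of genes. The p-values below are therefore over peaks or genes, not over flies. The peak lists give no read counts, so sequencing depth is unknown, and intervals cover counting error only.

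The authors' thresholded list, made from both replicates, held 6066 peaks on the dm6 build: 1105 on 2L, 1303 on 2R, 1337 on 3L, 1580 on 3R, 25 on chromosome 4 and 716 on X. Their signal values, which are the authors' own and serve here to rank and describe peaks within a list, had a median of 223 and ran from 141 to 4110.4. Most peaks (4776, or 78.7%) shared the highest −log10 q-value of the list, 3.98. These peaks are the ones described below unless another list is named.

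The strongest promoter peak was at CG14100 (3L 19590399-19590841, signal 4033), with its summit in intergenic sequence at −92 bp from the start. It was followed by Ugalt, which encodes a UDP-galactose transporter (X 2703684-2704100, signal 3036, summit at −20 bp), and yip2, a thiolase gene (2L 9915115-9915678, signal 2811), whose summit lay in an intron 174 bp downstream of the start. Next came eIF6, a factor of 60S ribosomal subunit maturation (signal 2733), and mRpL41, which encodes a mitochondrial ribosomal protein (2729.8, summit at −139 bp). The remaining leading promoter genes were CG1888, CG18428, Sox14, Lpin, Tcs5, CG31145, Chro, Gapdh2, Art3, Pdrg1, CG13390, CG1635, amon, CG3552, CG5611, CG11309, Glyp, CenG1A, Trp1 and Acsf2, with signal values from 2669 at CG1888 down to 1697 at Acsf2. Among them Lpin encodes a phosphatidate phosphatase, Gapdh2 a glycolytic enzyme, Glyp glycogen phosphorylase and Chro a chromodomain protein. The 60 bp at the CG14100 summit (3L 19590586-19590645) read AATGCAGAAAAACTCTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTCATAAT.

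Whether the replicates marked the same places was asked of each one's 5000 peaks of highest signal value. Of replicate 1's leading peaks, 3333 (66.7%) shared at least 1 base with one of replicate 2, against 2.79% ± 0.267 (SD over 200 shifts along the arms) by chance (one-sided permutation p = 0.00498, the smallest these shifts can give). At CG14100 the peak ranked 6 in replicate 1 and 1 in replicate 2, and at yip2 it ranked 2 and 34. At Hsp83, which encodes the Hsp90 chaperone, the ranks were 8 and 291. Signal values of the 5973 peaks matched in both had a Spearman's rho of 0.30 (95% bootstrap interval over peaks 0.273 to 0.327), across peaks that are not independent replicates. Over all 19671 matched peaks of the pooled list, a set chosen after seeing the data and not selected by the threshold, rho was 0.572, while within the 3033 thresholded peaks of lowest pooled signal it was -0.554.

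Peaks concentrated at promoters. No list from a mock immunoprecipitation was used here, so regions that an antibody against GFP recovers without the tagged protein were not removed. Of 6066 summits, 3362 (55.4%, Wilson interval 54.2 to 56.7) lay within 500 bp of the start of a protein-coding transcript, 4.83-fold the 11.5% ± 0.590 of the shifted summits (one-sided permutation p = 0.00498, the smallest possible). These summits had a median position of −54 bp from the nearest start, and 65.8% of them lay upstream. The share fell along the signal ranking, from 67.2% of the 500 strongest peaks to 49.9% of those ranked 4001 to 6066, and was 28.3% among the 23934 pooled peaks outside the thresholded list. Introns held 32.6% of summits, 0.822-fold the shifted share, and intergenic sequence 7.06%, or 0.25-fold. Coding exons held 0.758%, 0.0546-fold the shifted share, and 3′ UTRs held 1.37%, or 0.310-fold (one-sided permutation p = 0.00498 for each of these classes). The classes are exclusive and promoters come first, so the high promoter share by itself lowers the share left to the other classes. The fold of introns therefore does not show that summits outside promoters avoid introns. Outside promoters 1980 summits lay in introns, 428 in intergenic sequence, 83 in 3′ UTRs and 46 in coding exons. In the shifts these classes held 39.7%, 28.2%, 4.42% and 13.9% of all summits. Among summits outside promoters, introns thus held a larger part than in the shifts, a difference that was not tested. The 5′ UTR share of 1.09% was 1.40-fold the shifted share (one-sided permutation p = 0.0199), but at a promoter distance of 1000 bp it turned to 0.346% against 0.455% in the shifts.

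**Figure D1:**
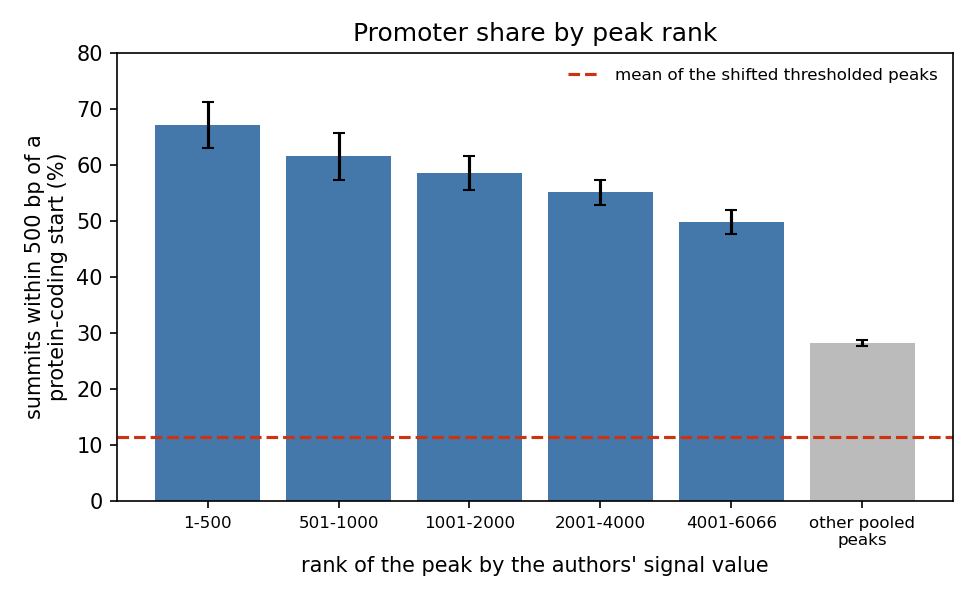
Percent of summits within 500 bp of a protein-coding start (vertical axis) by rank of the peak's signal value (horizontal axis). Bars show percent with 95% Wilson intervals, blue for the 6066 thresholded peaks and grey for the other pooled peaks, and the dashed line marks the mean of the shifted thresholded peaks, 11.5%; the share falls from 67.2% to 49.9% along the ranking.

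Among peaks far from promoters, 1374 (22.7% of summits) lay over 2000 bp from every protein-coding start. The strongest of them was on 3L at 3060566-3061025 (signal 2617), in an intron, 5706 bp downstream of the nearest start, that of CG16753. The next was in intergenic sequence on 2L at 2202031-2203057 (signal 2389), nearest CG31668. A peak on 3R at 29214207-29214646 (signal 2107) lay 5721 bp upstream of eEF1gamma, an elongation factor gene. The others of the leading 5 were intronic, at 2R 22569738-22570450, nearest CG11362, and at 2R 8060798-8061211, nearest CG12769.

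The locus of CG12768 itself (FBgn0037206, 3L 22910491-22923532, plus strand) held peaks in each list, and the tagged copy is a transgene of the same sequence. Summits of the thresholded list lay at −1026 bp from the gene's start (signal 556, rank 576), in an exon of other annotation, and in an intron 85 bp (238, rank 2736) and 329 bp downstream (173, rank 4482). Within the gene and 5 kb around it, replicate 1 had 12 peaks and replicate 2 had 4, and the pooled list had 7. Reads from the transgene and from the gene's own locus cannot be separated in these lists.

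Because males carry a single X, bound promoters were compared between the X and the autosomes. A protein-coding gene was counted as bound where a summit lay within 500 bp of one of its starts, which held for 3613 of 13945 genes (25.9%). Ugalt and Gapdh2 on X were among the strongest, but X genes were bound less often as a class. On X 390 of 2196 genes (17.8%) were bound, against 3204 of 11669 (27.5%) on the large autosome arms, an odds ratio of 0.571 (95% interval 0.508 to 0.642; Fisher's exact test, two-sided, p = 1.09e-22). The autosome arms ranged from 24.9% on 2L to 28.5% on 3L, and chromosome 4 had 19 of 80 genes bound. Both replicates gave the lower X value when used alone, each through its own 6066 leading peaks, with odds ratios of 0.604 without replicate 1 and 0.592 without replicate 2.

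**Figure D2:**
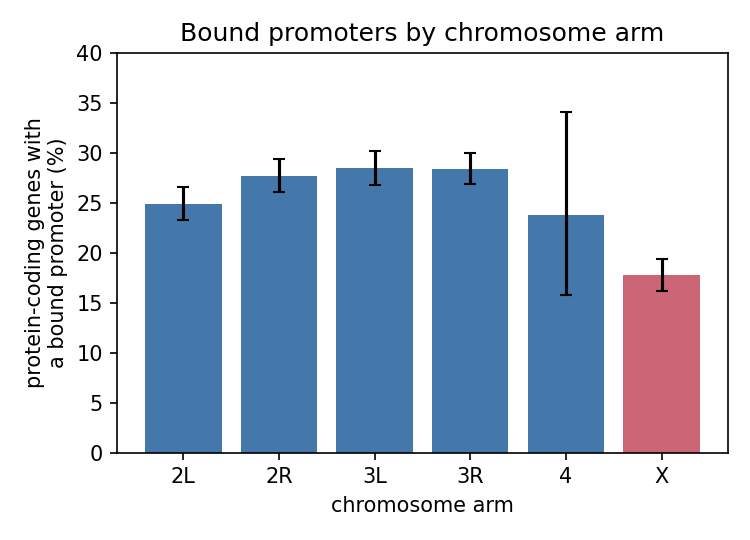
Percent of protein-coding genes with a bound promoter (vertical axis) on each chromosome arm (horizontal axis), with 95% Wilson intervals. The X, in red, stands at 17.8%, and the large autosome arms stand between 24.9% and 28.5%.

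Promoters in divergent pairs were bound more often than others. Of genes with the start of an opposite-strand gene within 1000 bp upstream, 1928 of 4650 (41.5%) were bound, against 1685 of 9295 (18.1%) of the others, an odds ratio of 3.20 (2.96 to 3.46; Fisher's exact test, two-sided, p = 5.35e-186). Such pairs included CG18428 with eIF4EHP and Art3 with mRpS10, each pair at 1 shared peak. One peak can thus count for both genes, and with each summit given to its nearest start, an alternative chosen after seeing the data, the odds ratio was 1.74. It was 4.24 without replicate 1 and 2.29 without replicate 2.

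Of 24 gene lists, 8 had bound promoters more often than other protein-coding genes and 6 less often. The list of histone genes could not be measured, and leaving it out, an alternative chosen after seeing the data, kept these 14 results. Cytoplasmic ribosomal protein genes stood highest, with 69 of 93 bound, against 25.6% of other genes (odds ratio 8.25, 5.20 to 13.1; Fisher's exact test, two-sided, adjusted p = 5.15e-21). RpS27 (signal 1083), RpL7 (796), RpL34b (771) and RpL14 (769) had the strongest peaks, with summits from −84 to 30 bp from the start. Other lists of translation and RNA genes passed as well. Of mitochondrial ribosomal protein genes 32 of 75 were bound, led by mRpL41, mRpS10, mRpS23 and mRpL23 (odds ratio 2.15, adjusted exact p = 0.00553), and of translation factor genes 23 of 54, led by eIF6 and eIF4EHP (2.14, adjusted exact p = 0.0155). Spliceosome genes had 14 of 28 bound, led by Phf5a and BCAS2 (2.87, adjusted exact p = 0.0155). The replicates differed here: mitochondrial ribosomal protein genes had 43 of 75 bound without replicate 1 (odds ratio 3.48, adjusted exact p = 4.48e-07) and 21 of 75 without replicate 2 (1.33, adjusted exact p = 0.365). Without replicate 1 spliceosome genes had 15 of 28 bound (2.97, adjusted exact p = 0.0107), and they had 6 of 28 without replicate 2 (0.973, adjusted exact p = 1).

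Genes of stress response, lysosome, chromatin architecture and the clock were also bound more often. Of heat shock and chaperone genes 18 of 36 were bound (adjusted exact p = 0.00553), with Hsp83 (signal 1640.3) and Hsp27 (1506) leading, and 16 of 36 without replicate 1 (adjusted exact p = 0.0547). Autophagy and lysosome genes had 27 of 58 bound (adjusted exact p = 0.00304), among them Atg17, Vha100-2, Atg2 and Vha36-1. Of architectural and core-promoter protein genes 11 of 23 were bound (adjusted exact p = 0.0455), among them Chro, Cp190, Dref and M1BP, and of circadian clock genes 8 of 14 (adjusted exact p = 0.0238), led by cry, a blue-light receptor gene (signal 1369), and vri (553).

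The lists bound less often included chemoreceptor genes, which had 2 of 180 bound, Ir60e and Gr63a (adjusted exact p = 1.27e-19), cuticle protein genes 3 of 122, Cpr51A, Lcp9 and Cpr73D (adjusted exact p = 1.26e-11), and accessory gland genes 1 of 42, Sfp26Ad (adjusted exact p = 0.00056). With each summit given to its nearest start, these lists had 0 of 180, 1 of 122 and 0 of 42 bound and still passed. The peaks at Ir60e, Gr63a and Sfp26Ad are then assigned to other genes. Male germline genes had 4 of 48 bound (adjusted exact p = 0.0104): bol, bgcn, Prtl99C and cher, the last of which encodes filamin and is used in many tissues. Polycomb-regulated developmental genes had 7 of 71 bound, led by hb and Dll (adjusted exact p = 0.00351), and digestive enzyme genes 7 of 57, led by Mal-A5 and kappaTry (adjusted exact p = 0.0265), or 9 of 57 without replicate 2 (adjusted exact p = 0.365). The 111 replication-dependent histone genes are near-identical copies in a cluster on 2L at 21416953-21541681, in which neither replicate's list of 30000 peaks nor the pooled list had a summit, so whether they were bound was not measured.

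The other 9 lists did not pass the test. The MADF-BESS list, the family of CG12768, had 9 of 19 members bound, among them brwl (signal 865) and hng3 (795), with an adjusted exact p of 0.0817, with 11 of 19 without replicate 1 (odds ratio 3.50, adjusted exact p = 0.0156) and 6 of 19 without replicate 2 (1.62, adjusted exact p = 0.469). At 250 bp it had 5 of 19 (adjusted exact p = 0.664), and in the 3033 peaks of highest signal 3 of 19 (adjusted exact p = 1). The 9 include CG12768 itself, and with it left out, an alternative chosen after seeing the data, 8 of 18 were bound (adjusted exact p = 0.122). Ecdysone response genes had 10 of 22 bound (adjusted exact p = 0.0691, and 0.0423 without replicate 2), including EcR and Eip93F. They also passed with each summit given to its nearest start (odds ratio 3.37, adjusted exact p = 0.0162). They did not pass without replicate 1 (adjusted exact p = 0.111), at 250 bp (0.163), at 1000 bp (0.0773) or in the 3033 peaks of highest signal (0.467). The adjusted exact p of the others follows each count: fat body genes 10 of 24 (0.12), including Tret1-1 and Adh, DNA replication genes 13 of 39 (0.317), including dpa and dup, and dosage compensation genes 3 of 8 (0.474): JIL-1, Sxl and Clamp. Oxidative phosphorylation genes had 26 of 94 bound (0.723), including ND-ASHI and ND-42, proteasome genes 10 of 48 (0.533, with an odds ratio of 0.779, but 1.44 without replicate 1 and 0.608 without replicate 2), including Rpt5 and Rpn5, muscle genes 4 of 33 (0.0946), including Argk1 and Msp300, and neuronal genes 5 of 43 (adjusted exact p = 0.0527, and 0.0275 without replicate 1), including elav and Nrx-1. Neuronal genes also passed as lower at 250 bp (2 of 43, odds ratio 0.218, adjusted exact p = 0.012) and at 1000 bp (6 of 43, adjusted exact p = 0.0423). They did not pass without replicate 2 (adjusted exact p = 0.16), in the 3033 peaks of highest signal (0.474), with nearest starts (0.299) or with members within 10 kb counted once (0.076).

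These list results depended on the processing. Against only those genes with any summit of the pooled list at a start, 3 lists passed: ribosomal proteins (69 of 85 bound, odds ratio 4.93, adjusted exact p = 9.49e-10) higher, and neuronal (5 of 33, adjusted exact p = 0.00334) and digestive enzyme genes (7 of 37, adjusted exact p = 0.00537) lower. Of the lists lost there, cuticle protein genes had 3 of 8 bound (odds ratio 0.734, from 0.0829), chemoreceptor genes 2 of 12 (0.274, from 0.0394) and male germline genes 4 of 11 (0.692, from 0.288). Heat shock (2.52, from 2.87) and autophagy genes (2.20, from 2.51) changed less. Every thresholded peak is in the pooled list, so this background leaves out unbound genes only. Cuticle protein genes fell from 122 to 8 members and chemoreceptor genes from 180 to 12. Loss of a lower list there is thus no evidence against its lower binding among all genes. Accessory gland genes, with 2 members left, and histone genes were too few to be tested there. With each summit given to its nearest start, mitochondrial ribosomal protein genes had 11 of 75 bound (odds ratio 0.712), and the mitochondrial ribosomal, spliceosome, architectural, autophagy, male germline, digestive enzyme and Polycomb-regulated lists no longer passed. With members within 10 kb of each other counted once, because neighbours can share a peak or a domain, digestive enzyme genes had 5 of 25 bound (odds ratio 0.765, adjusted exact p = 0.649), male germline genes 4 of 38 (adjusted exact p = 0.0509) and circadian clock genes 7 of 13 (adjusted exact p = 0.076), none of them past the threshold, and cuticle protein genes 3 of 49 (odds ratio 0.213, from 0.0829; adjusted exact p = 0.00299). At 250 bp the spliceosome, heat shock, architectural and circadian lists no longer passed, nor in the 3033 peaks of highest signal did the spliceosome, heat shock and autophagy lists.

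**Figure D3:**
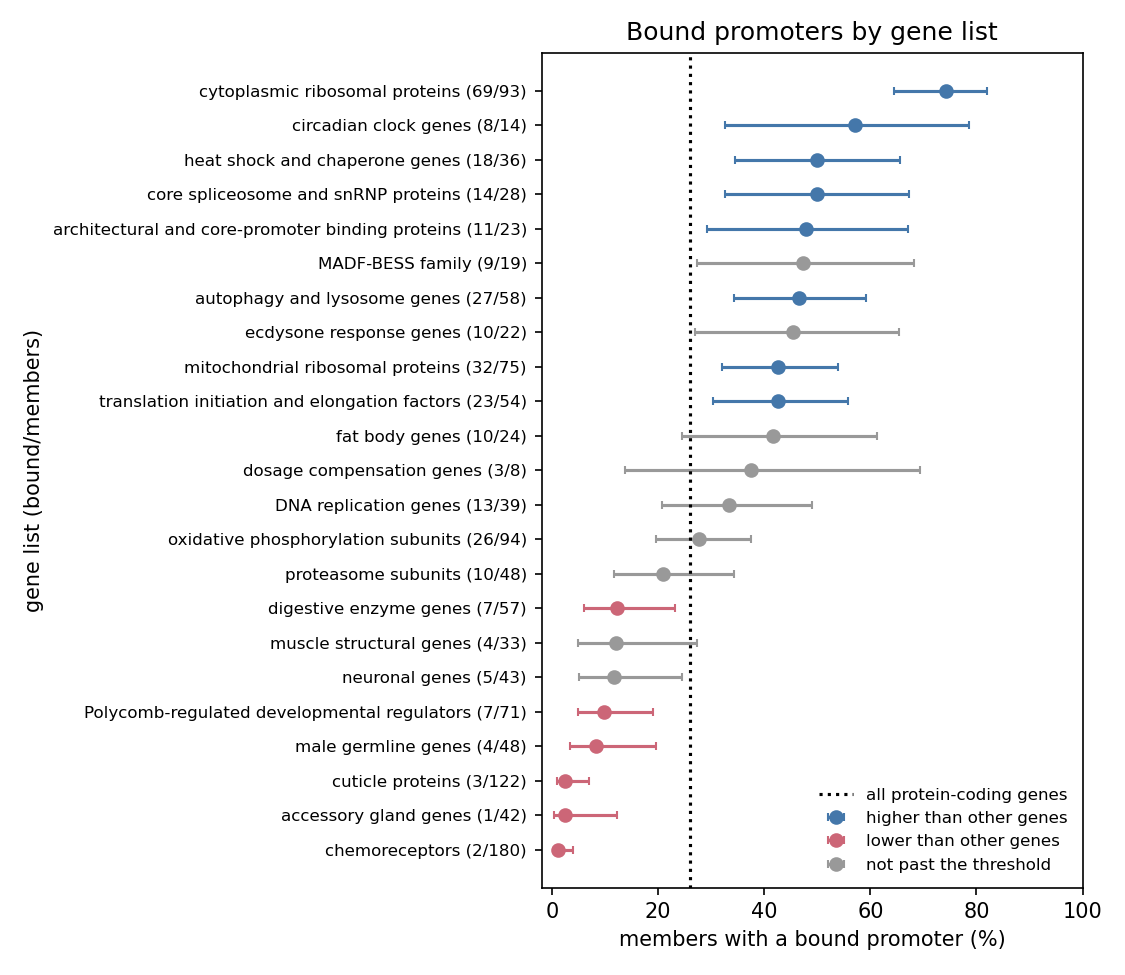
Percent of each gene list's members with a bound promoter (horizontal axis) for each list but that of histone genes, which was not measured (vertical axis, with bound and total members), with 95% Wilson intervals. Blue lists were bound more often and red lists less often than other genes, grey lists did not pass the test, and the dotted line marks 25.9% of all protein-coding genes; cytoplasmic ribosomal proteins stand highest.

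Sequence at the summits differed from that beside them. Of 24 motifs, 11 were more frequent in the 200 bp at the summit than in flanks centred 500 bp away, and 1 was less frequent. The DNA replication-related element (DRE, TATCGATA) was found at 2.74% of summits and 0.808% of flanks (exact McNemar test, two-sided, adjusted p = 3.82e-15). The GAGA element was found at 8.62% and 4.29% (adjusted exact p = 1.57e-21) and the core promoter element Motif 7 at 6.51% and 3.41% (adjusted exact p = 1.92e-14). The Initiator, GATA, TATA, CAGCTG, CA-repeat, Motif 1, Motif 6 and ATCGAT sequences were also more frequent, and the Zelda motif was less frequent (0.791% and 1.45%, adjusted exact p = 0.00236), though not past the threshold in a 100 bp window (adjusted exact p = 0.105), where its ratio was 0.573, from 0.538. ATCGAT lies within the DRE and is no separate result: it was found at 501 summits and 428 flanks, and the DRE at 166 and 49. Windows with a DRE thus hold all of the ATCGAT excess. The GCC repeat of the Adf1 type was found at 6.43% of summits and 6.45% of flanks (exact p = 1), but the replicates alone went opposite ways: 5.47% and 6.51% without replicate 1 (adjusted exact p = 0.0381) and 7.52% and 5.82% without replicate 2 (adjusted exact p = 0.000446). The DRE stood at 3.84% and 0.692% without replicate 1 and at 1.76% and 1.06% without replicate 2. The CA repeat, CAGCTG and Initiator did not pass without replicate 1, nor did the ATCGAT, Motif 6 and TATA sequences without replicate 2. The ATCGAT, Motif 1, Motif 6, CAGCTG and CA-repeat sequences passed neither in the 3033 peaks of highest signal nor in a 100 bp window, and Motif 6 and CAGCTG did not pass against flanks 1000 bp away. Ratios in the full list, the 3033 peaks and the 100 bp window were 2.01, 2.03 and 2.12 for Motif 1, and 1.59, 1.51 and 1.83 for Motif 6. They were 1.18, 1.20 and 1.15 for ATCGAT, 1.21, 1.12 and 1.19 for CAGCTG, and 1.28, 1.23 and 1.07 for the CA repeat.

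Promoters that were not bound hold many of the same elements. Against such promoters matched for GC content and position, over 3348 promoter peaks, Motif 7, GAGA, CA-repeat, CAGCTG and GATA sequences were again more frequent at summits, and so was the Ets motif (1.22% and 0.597%, adjusted exact p = 0.0296). The DRE was not past the threshold there (4.57% and 4.0%, adjusted exact p = 0.453), nor was the Zelda motif (0.747% and 0.836%, adjusted exact p = 0.818), and the TATA box was less frequent (3.91% and 7.17%, adjusted exact p = 4.58e-08), as was the Initiator (21.03% and 23.9%, adjusted exact p = 0.0166). In the 1000 peaks of highest signal, a set chosen after seeing the data, the A tract alone passed.

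A search over all words of 8 bases, ranked on 2L and 2R, placed CAACACTG first. On the 3633 peaks of 3L, 3R and X, which had no part in the ranking, it was found at 3.33% of summits and 0.606% of flanks (exact McNemar test, two-sided, adjusted p = 1.2e-17). The overlapping word AGTGTTGG was found at 2.26% and 0.495% (adjusted exact p = 3.07e-10). The other words of the leading 10 held GAGA-type repeats or CAGCTG, and all 10 passed the test on these peaks. Words were compared with flanks only. Whether they are more frequent at bound promoters than at matched unbound promoters was not tested. Without replicate 1 CAACACTG again led, and without replicate 2 the CA repeat CACACACA led, with CAACACTG at 2.36% of summits and 0.639% of flanks. In the 1000 peaks of highest signal, a set chosen after seeing the data, ATTTAAAA led. Most of the leading 10 words there were rich in A and T, and CAACACTG was not among them. CAACACTG was still more frequent at summits than in flanks in these peaks. It stood at 3% and 0.8% at ranks 1 to 500, and at 4.2% and 0.6% at ranks 501 to 1000. These shares include the peaks of 2L and 2R that ranked the words, so they are no separate test.

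The authors processed the reads on both the dm6 and the dm3 build. The dm3 thresholded list held 5056 peaks, 0.833 of the dm6 count, and the ratio ran from 0.827 on 3R to 0.838 on 2L among the X and the large autosome arms. Chromosome 4 had 12 peaks on dm3 and 25 on dm6.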

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

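No test was run in this part. The dm3 thresholded list held 5 peaks on the unplaced sequence Uextra, which is outside the chromosome arms used in the comparisons and was not analysed. It also held 1 peak on 2RHet and 1 on U, and the dm6 thresholded list held 0 peaks outside the arms. None of the dm6 lists had a peak on unplaced sequence, so that 0 is no benchmark for the dm3 count.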

How the results depend on the processing

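The nearest-start assignment, the shifts within the span of the summits, the 1000 strongest peaks, the rank correlation over the pooled list, the lists without histone genes, the families without CG12768 and the family defined by similarity were chosen after seeing the data; the other alternatives were not. The promoter share, the lower binding on X and the higher binding of divergent genes kept their direction and their side of the threshold under every alternative run. With 1 replicate left out, the promoter share was 53.7 to 56.6%, the X odds ratio 0.592 to 0.604, the divergent odds ratio 2.29 to 4.24, the count of gene lists passing 13 to 16 and that of motifs 11 to 13, and 10 words passed each time. The rank correlation was 0.343 with summits within 100 bp, 0.232 in the 3033 peaks of highest signal, -0.554 in the 3033 of lowest signal and 0.572 over the pooled list. The negative value follows from the selection: within a narrow range of pooled signal, a peak high in 1 replicate must be low in the other. The 5′ UTR share was 0.346% at 1000 bp, below its shifted share, and 0.890% in the 3033 peaks of highest signal, no longer past the threshold; the cause was not tested. Gene lists passing numbered 9 with nearest starts (8 of them among the original 15) and 3 against genes of the pooled list (2 of them among the original 15). The pooled-list background leaves out unbound genes only. Counts of lists other than the last include the histone list, which could not be measured; without it 14 passed. Motifs passing numbered 6 in a 100 bp window and 1 in the 1000 strongest peaks, none of the latter among the original 12, and words 5 in a 100 bp window; smaller windows and fewer peaks give fewer sites, and other causes were not tested. In the 1000 strongest peaks 7 words passed, led by ATTTAAAA in place of CAACACTG. The dm3 to dm6 ratio was 0.979 at signal values of at least 223, which rests on the untested assumption that signal values have the same scale on both builds. Reversed odds ratios or ratios, their causes not tested, were: spliceosome with 1 replicate left out, 0.973 to 2.97; mitochondrial ribosomal proteins with nearest starts, 0.712; and, with 1 replicate left out, CA repeat 0.945 to 1.78, ATCGAT 0.857 to 1.78 and Motif 6 0.898 to 1.56. Against matched unbound promoters they were ATCGAT 0.968, Motif 1 0.902, Motif 6 0.816, TATA box 0.531 and Initiator 0.845. In the 1000 strongest peaks they were ATCGAT 0.893, Motif 1 0.455, CAGCTG 0.873 and CA repeat 0.868. That Motif 1 ratio rests on 0.2% of summits and 0.5% of flanks. Of all these reversed values, only the TATA box and Initiator ratios against matched unbound promoters were past the threshold. Over single lists and motifs in all alternatives, those above included, 145 results past the threshold stayed past it in the same direction, 2 passed in the other direction, 68 were no longer past it and 17 came past it. Of values past it in neither setting, 125 kept their side of 1 and 23 did not. Depth is unknown, so whether the weaker ranks are limited by reads is open.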

Other observations

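The family by sequence similarity, the families without CG12768, the non-coding starts, the comparisons of peaks leading in 1 replicate alone, by promoter too, and the thinned chromosome 4 peaks were chosen after the data were seen, and the test of the Het, U and Uextra sequences after its own result was seen. The family of CG12768 by sequence similarity, in place of the fixed MADF-BESS list, held 46 genes, of which 26 (56.5%) were bound, against 25.8% of other genes (odds ratio 3.72, 2.09 to 6.62; Fisher's exact test, two-sided, p = 1.11e-05). This definition was tried after the fixed list, with 9 of 19 bound, had missed its threshold (adjusted exact p = 0.0817), so its p is not that of a planned test. Without CG12768, whose locus cannot be separated from the transgene, 25 of 45 were bound (odds ratio 3.58, exact p = 2.37e-05). The fixed list had 11 of 19 bound without replicate 1 and 6 of 19 without replicate 2.

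Some kinds of non-coding genes had bound starts as well. A summit lay within 500 bp of 51 of 290 tRNA gene starts (17.6%), 4.10-fold the shifted share (one-sided permutation p = 0.00498, the smallest possible), and of 324 of 3388 ncRNA starts (2.31-fold), 25 of 270 snoRNA starts (2.24-fold, one-sided permutation p = 0.0348) and 5 of 32 snRNA starts (3.61-fold, one-sided permutation p = 0.0398). The p-values of this paragraph are not adjusted for the number of kinds tried. The observed shares of snoRNA (9.26%) and snRNA starts (15.6%) were below the highest shifted shares, 12.2% and 25%. The hypothesis that tRNA genes are marked because they lie near bound protein-coding promoters was tested on the 167 tRNA starts over 2000 bp from every such promoter. Of these 13.2% had a summit, against a mean of 4.26% and a highest value of 12.0% in the 200 shifts, so nearness to protein-coding promoters does not account for all of the tRNA signal. Distant ncRNA starts had a summit in 5.08% of cases (1.23-fold, one-sided permutation p = 0.0896), distant snoRNA starts in 2.20% (0.517-fold, one-sided permutation p = 0.746) and 2 of 20 distant snRNA starts had one (one-sided permutation p = 0.214), while pseudogene starts at any distance had one in 3.64% (0.931-fold, one-sided permutation p = 0.567).

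The empty histone cluster was also tested. The pooled list of 30000 peaks had 0 summits in it, where 1000 windows of the same size on 2L held a median of 30 and none was empty, which is consistent with reads shared between near-identical copies being left out before peaks were called (0 pooled-list summits in the cluster). Binding at histone genes therefore stays unmeasured.

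The replicates differed in the sequence content of their leading peaks. Of each one's 5000 leading peaks, those with no counterpart among the other's 5000 are called alone here. They can still match a weaker peak in the other's list of 30000. The 1691 of replicate 2 alone held a DRE in 5.50% of cases, and the 1667 of replicate 1 alone in 0.66% (odds ratio 8.43, Fisher's exact test, two-sided, adjusted p = 1.27e-16). GAGA elements went the other way, 2.84% against 11.3% (adjusted exact p = 2.35e-21), and 60.5% of summits in replicate 2 alone were at promoters, against 47.7% in replicate 1 alone (odds ratio 1.68, exact p = 1.16e-13). GC content also differed, 36.5% ± 7.45 in replicate 2 alone and 45.5% ± 6.59 in replicate 1 alone (SD over peaks), but with GC content stratified the DRE odds ratio was still 8.08 (3.88 to 16.8), and with promoter and other peaks stratified it was 7.44 (3.95 to 14.04), which argues against GC content and against the promoter share as the whole cause, each taken alone. Noise near the end of the lists is argued against too: among 3727 thresholded peaks leading in both replicates, the log2 ratio of replicate 2 over replicate 1 was higher by 0.40 (0.25 to 0.54) with a DRE than without. A difference between the preparations or the flies may remain, which the labels do not record, and no biological explanation was tested because there is 1 group.

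Replicate 2 had 518 peaks on chromosome 4 and replicate 1 had 48. More recovery of heterochromatic sequence in general would raise the dm3 Het, U and Uextra sequences too, but replicate 2 had 34 peaks there and replicate 1 had 181, a ratio of 0.188. Replicate 2's peaks there had a median rank of 18580 of 30000, which shows that they were weak but does not tell weak and widespread enrichment from background. Thinned at random to 48 peaks, they lay in a median of 37 of the bins of 10 kb that hold a gene (95% of draws 33 to 42), against 20 in replicate 1 and 40 (35 to 44) for peaks placed at random over these bins, so at equal numbers the peaks of replicate 2 were spread more evenly along chromosome 4 than those of replicate 1 and about as evenly as random placement gives. Replicate 1's peaks there had a median rank of 11910 in its list, so equal numbers were not equal ranks. Evenness at equal rank was not compared. In the 12 thresholded peaks of chromosome 4 matched in both replicates, the log2 ratio of replicate 2 over replicate 1 had a median of 0.08, against -0.14 elsewhere (two-sided permutation p = 0.571); the lower GC content of replicate 2's peaks stays open as a source, and no biological explanation was tested.

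Lower binding on X may reflect the single X of males, which would lower the signal at every site if signal values follow the reads recovered. Their scaling is not stated, and a value taken relative to the control need not fall with copy number. The promoter signal that the strongest 10% of genes exceed in the pooled list was, on X, 0.653 of the autosomal value (95% bootstrap interval 0.596 to 0.720). That is above the 0.5 that a single copy alone predicts where signal follows reads, and below equality. Dose and weaker binding therefore cannot be told apart without females, and no biological explanation was tested. Among genes in no list, 362 of 2053 on X (17.6%) and 2920 of 10484 on the large autosome arms (27.9%) were bound, an odds ratio of 0.555 (0.492 to 0.627). Lower binding on X is thus also found outside the listed genes. Most genes are in no list, and lists bound less often were left out along with those bound more often. Leaving them out could hardly change the odds ratio, so whether a lack of the lists bound more often adds to the difference was not decided.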
